A study of Mus musculus with 4 samples.

How the data were processed

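Gene expression was measured in mouse soleus muscle, a slow-twitch calf muscle, on 4 arrays. Per the labels, each array is a technical duplicate of soleus muscle pooled from 5 female mice aged 6 months. The arrays of a genotype were therefore taken as duplicates of a single pool, which gives 1 biological sample (pool) and 2 arrays per genotype. HSL is hormone-sensitive lipase, the product of Lipe.

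The deposited table holds 1 linear intensity for each of 12488 probe sets on each array. The values were already scaled when deposited: with 2% of the values trimmed from each end, every array had a mean of 100, as tested on the values. The software, the background correction and the step that made these means equal are not given in the sources used here. Between 1 and 3 probe sets per array were listed at 0, and the highest intensity per array lay between 5646 and 6183. No detection calls were used. The number of arrays limits the precision, and the spread between duplicates measures the error of the arrays, not the variation between animals.

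Probe sets were named through the platform annotation, in which 10855 probe sets had 1 gene symbol, 396 had several and 1237 were not listed, 44 of them control probe sets. The symbols of 10839 probe sets were matched by gene ID to a RefSeq gene table (assembly GRCm38.p6), which was used only for names and for the order of neighbouring genes. No genome build is named in the sources used here, so that no coordinates are given. Probe sets with the suffixes _f, _r, _i, _g and _s can share probes with related sequences, and values of gene families such as the myosin heavy chains are uncertain to that extent.

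The trimmed means lay within the tolerance of 5% set for using the values as deposited. Values were floored at the 25th percentile of the table (intensity 5.70) and transformed to log2. The 66 control probe sets were left out. Probe sets with a mean over the 4 arrays at or above the median of all probe sets (intensity 27.7) were kept, which left 6208 probe sets and 4851 named genes. With 1 pool per genotype no test across animals was possible, and no p-value was computed. A probe set was called separated when all 4 differences between an HSL-null and a wildtype array had one sign and the smallest was at least 1.5-fold. The count under the 2 other ways of splitting the 4 arrays into pairs, each of which mixes the genotypes, gave the level that noise between arrays produces. Errors are SDs over 2 arrays for intensities and standard errors from the duplicates for log2 differences.

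The 32 gene lists (645 entries), the rules, the naming of genes and the alternatives were fixed before the data were examined, except where said otherwise. A gene was represented in its list by the probe set with the highest mean. For the 30 lists with at least 3 members above the filter, the median log2 difference was set against 10000 random lists of the same size, matched on level in 10 bins. The percentile describes these pools only, and a list was called outside the central 95% below percentile 2.5 or above 97.5. The genes named were Lipe, the 12 highest and the 12 lowest genes among separated probe sets with 1 symbol and every array above the floor, and up to 3 bounds per direction for probe sets at the floor in one pool, of which 0 were found. In each list the separated members were named, at most the 4 with the largest difference, or, where there were none, the 2 with the highest level. Genes outside this rule are said to have been chosen after their values were seen.

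The separation rule was tested on simulated data with the real levels and the noise of the duplicates, over 6208 probe sets with 50 changed per fold. It recovered 14% of those changed 1.5-fold, 84% of those changed 2-fold and 100% of those changed 3-fold, and it called 2 of 6008 unchanged probe sets. The simulated noise was normal, with an SD set by level only. Under the 2 other splits of the real arrays the rule called 13 and 12 of 6208 probe sets. The simulated rate of false calls is therefore too low for the real arrays. Alternatives covered median centring, a common trimmed mean, quantile normalization and cyclic loess (limma 3.58.1 in R 4.3.3), the floor, the filter, the size threshold, each array left out, the replicate number as a block, and the probe set that stands for a gene. Values of 0 were set to 0.1 before quantile normalization and loess. Lists without Lipe were an alternative chosen after seeing the data. Computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. No array was left out of the comparisons.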

Results

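Soleus muscle RNA of wildtype and HSL-null mice was compared on 4 arrays, 2 per genotype. HSL (hormone-sensitive lipase) hydrolyses stored acylglycerols and cholesteryl esters, and the comparison asks how the muscle transcriptome differs without it. Each genotype was represented by 1 pool of muscle from 5 mice, so that no difference below has a replicate check across animals. Across 6208 probe sets, which are not independent replicates, duplicate arrays correlated at r = 0.987 for wildtype and 0.988 for HSL-null, and arrays of different genotypes at 0.983 to 0.986. The SD of the log2 difference between duplicates was 0.26 for wildtype and 0.25 for HSL-null, against 0.27 to 0.30 between single arrays of different genotypes. As a measure of RNA quality, the ratio of 3′ to 5′ signal of the beta-actin control was 0.697 ± 0.0126 (SD, n = 2 arrays) in wildtype and 0.819 ± 0.00532 in HSL-null. The same ratio for Gapdh was 0.941 ± 0.0203 in wildtype and 0.917 ± 0.00716 in HSL-null. The pools thus differed in opposite directions on these controls, but hardly for Gapdh, whose ratio was 0.927 on wildtype array 2 and 0.922 on HSL-null array 1. Here and below, the lower Gapdh ratio therefore does not offset the higher beta-actin ratio.

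The targeted gene was examined first. Lipe, which encodes HSL, measured 71.4 and 70.2 on the wildtype arrays and 16.2 and 19.4 on the HSL-null arrays. Its level was 70.8 ± 0.849 (SD, n = 2 arrays) in wildtype and 17.8 ± 2.26 in HSL-null, 3.99-fold lower (log2 difference -2.00 ± 0.13, SE of duplicates). The signal left in HSL-null lay above the floor of 5.7. The lower level on every array pair goes with the genotype labels. Lipe is also a white adipocyte marker, however, and those markers were lower as a list. The labels do not say which part of the gene was disrupted, so whether the probe set lies in that part is not known.

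Few genes were separated between the pools. Genes of fast muscle fibres, led by Myh4, were among those higher in HSL-null, and Lipe, adipocyte and fatty acid synthesis genes were among those lower. Of 6208 probe sets, 28 were separated, 14 higher and 14 lower in HSL-null, and these covered 12 named genes higher and 13 lower. The rule recovered 14% of simulated 1.5-fold changes, so that this count does not show that few genes differed. The 2 other splits of the arrays gave 13 and 12 separated probe sets, so that noise between arrays alone can separate a single probe set. Of 30 gene lists, 9 had a median outside the central 95% of random lists, against 2 (fast-twitch and slow-twitch fibre) and 2 (insulin signalling, and the unfolded protein response) under the other splits.

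Fast-twitch fibre genes were higher in the HSL-null pool as a list, with 3 separated members. Myh4, the myosin heavy chain of the fastest glycolytic fibres, measured 278 ± 1.34 (SD, n = 2 arrays) in wildtype and 1839 ± 81.7 in HSL-null, 6.61-fold higher (log2 difference 2.72 ± 0.046, SE of duplicates). Actn3, the alpha-actinin of fast fibres, measured 361 ± 34.5 in wildtype and 1097 ± 26.5 in HSL-null, 3.05-fold higher, and its second probe set was 1.85-fold higher and also separated. Pvalb, the calcium buffer parvalbumin of fast fibres, was 2.29-fold higher on one probe set and 1.69-fold higher on its brighter one, from 1320 ± 45.3 to 2227 ± 38.6. The second Myh4 probe set, at 26.9 ± 1.27 in wildtype and close to the filter, differed by 0.15 ± 0.15 and was not separated. Of 15 fast-twitch genes above the filter, 3 were separated higher, 0 lower and 12 neither, and 14 lay above 0 (13 with median centring, 12 with quantile normalization). Their median was 0.11, at percentile 99.9, and 0.073 and 0.056 with these scalings. One of the other splits also put this list outside the central 95%, at -0.053 (percentile 1.74), and slow-twitch fibre at -0.077 (percentile 0.0400). Other fast-twitch genes, chosen after their values were seen, were Atp2a1 at 0.053 ± 0.059, Tnnt3 at 0.044 ± 0.10 and the single member below 0, Mylpf, at -0.27 ± 0.24. Atp2a1 measured 4969 ± 284 in wildtype and 5152 ± 26.7 in HSL-null, and Tnnt3 4124 ± 416 and 4240 ± 22.8. Levels this close to the highest intensity on the arrays (5646 to 6183) may hide a change, most of all for Atp2a1. The pool with these higher levels also had the higher beta-actin ratio (0.819 against 0.697), but the lower Gapdh ratio. The list lay inside the central 95% under quantile normalization (percentile 97.3), without wildtype array 2 (97.4) and without HSL-null array 1 (96.6).

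Slow-twitch fibre genes gave no separated member among 16. Tnnt1, the slow troponin T, measured 5867 ± 313 (SD, n = 2 arrays) in wildtype and 6062 ± 172 in HSL-null, and Myh7, the slow myosin heavy chain, 5122 ± 330 and 5201 ± 92.6. Both lie near the highest intensity on the arrays (5646 to 6183), where a change may not show. With the values as deposited, 10 members lay above 0 and 6 below, and each of the 6 was dimmer than the 10. This order by level was seen after the values were examined. Of the 16, 4 lay below 0 on all 4 array pairs (6 with quantile normalization). The 4 were Csrp3 (-0.36 ± 0.13), Myl6b (-0.29 ± 0.082), Ankrd2 (-0.26 ± 0.043) and Myh6 (-0.20 ± 0.086), and they did so under each of the 4 other scalings too. Above 0 on all 4 pairs were 3, Tpm3 (0.093 ± 0.062), Tnnc1 (0.089 ± 0.036) and Tnni1 (0.069 ± 0.034), but 0 with median centring and 0 with quantile normalization. These 7 were chosen after their values were seen. The list's median was 0.016, at percentile 45.1, and its mean -0.074. The median had the opposite sign with median centring (-0.017), quantile normalization (-0.035) and cyclic loess (-0.016), so that no direction was given.

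Adipocyte genes were lower in the HSL-null pool as a list. Adipoq, which encodes the adipocyte hormone adiponectin, measured 154 ± 4.95 (SD, n = 2 arrays) in wildtype and 73.8 ± 0.424 in HSL-null, 2.08-fold lower (log2 difference -1.06 ± 0.033, SE of duplicates). Of 8 white adipocyte markers above the filter, 2 (Lipe and Adipoq) were separated lower, 0 higher and 6 neither, and 7 lay below 0. Their median of -0.30 lay below those of all 10000 random lists. Without Lipe, an alternative added after the data were seen, the median was -0.25, at percentile 0.110. Members chosen after their values were seen were Cebpa at -0.35 ± 0.092, Fabp4 at -0.18 ± 0.11, Lep at -0.10 ± 0.21 and the exception Agt at 0.98 ± 0.32. Of the brown adipocyte markers, 2 were above the filter, Cidea at -0.061 ± 0.24 and Cox7a1 at 0.034 ± 0.047, too few for a list value. The pool with the lower adipocyte levels had the higher beta-actin ratio (0.819 against 0.697), but the lower Gapdh ratio.

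Fatty acid synthesis genes were lower in the HSL-null pool as a list too. Fasn, the fatty acid synthase, measured 161 ± 2.62 (SD, n = 2 arrays) in wildtype and 80.4 ± 6.43 in HSL-null, 2.00-fold lower. Scd1, the stearoyl-CoA desaturase, was 1.72-fold lower on one probe set, from 490 ± 15.1 to 286 ± 22.9, and differed by -0.74 ± 0.18 on its brightest probe set, which was not separated and stands for the gene in the lists. All 10 members above the filter lay below 0, 1 of them separated, and the median was -0.13, at percentile 1.93. The list shares 2 of these genes, Scd1 and Thrsp, with the white adipocyte markers. Its lower levels stood beside the same beta-actin ratios (0.819 in HSL-null, 0.697 in wildtype), with the Gapdh ratio lower in HSL-null. The list lay inside the central 95% under quantile normalization (percentile 3.16), with the filter at the 75th percentile (7.26), without wildtype array 1 (2.67), without wildtype array 2 (3.77) and without HSL-null array 2 (3.26).

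The lists of lipolysis, triglyceride synthesis, fatty acid uptake, PPAR targets, peroxisomal oxidation and cholesterol lay inside the central 95%. Among 11 lipolysis and lipid droplet genes Lipe was the single separated member, and the list had a median of 0.018 (percentile 66.7) and a mean of the opposite sign, -0.17. Pnpla2, which encodes adipose triglyceride lipase and was chosen after its values were seen, measured 1218 ± 46.6 (SD, n = 2 arrays) in wildtype and 1216 ± 54.0 in HSL-null. Triglyceride synthesis genes had a median of 0.056 (percentile 89.5), with Gpam at 0.21 ± 0.012 and Plpp1 at 0.57 ± 0.034. Fatty acid uptake genes had a median of 0.057 (percentile 86.4), with Fabp3 at 0.059 ± 0.053 and Cav1 at 0.071 ± 0.048. PPAR targets had a median of 0.074 (percentile 93.9), with Fabp3 again and Lpl at 0.097 ± 0.089. Peroxisomal oxidation genes had a median of 0.067 (percentile 95.4), with Ech1 at 0.068 ± 0.051 and Abcd3 at 0.029 ± 0.089. Cholesterol synthesis and uptake genes had a median of -0.041 (percentile 29.3), with Fdft1 at -0.041 ± 0.049 and Fdps at -0.076 ± 0.043.

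Mitochondrial lists lay above 0 by small amounts that depended on the scaling, with 0 separated members. The 17 genes of mitochondrial fatty acid oxidation had a median of 0.090 (percentile 99.8), and 14 lay above 0. Among them Acadm, the medium-chain acyl-CoA dehydrogenase, differed by 0.15 ± 0.011 and Acaa2, a mitochondrial thiolase, by 0.12 ± 0.037. The 20 genes of the TCA cycle and pyruvate dehydrogenase had a median of 0.085 (percentile 99.5), with 18 above 0, Mdh2 at 0.093 ± 0.056 and Idh2 at 0.13 ± 0.017. The 51 oxidative phosphorylation genes had a median of 0.050 (percentile 98.7), with 40 above 0, Cox6a2 at 0.099 ± 0.072 and Ndufb5 at -0.023 ± 0.059. With median centring the medians were 0.057, 0.051 and 0.016, with 12, 16 and 30 genes above 0, and with quantile normalization 0.060, 0.052 and 0.012, with 14, 15 and 30. These lists too were higher in the pool with the higher beta-actin ratio (0.819 against 0.697), which had the lower Gapdh ratio. The TCA list lay inside the central 95% without wildtype array 2 (percentile 96.9). The oxidative phosphorylation list did so under 7 of 17 alternatives, among them quantile normalization (85.1) and leaving out wildtype array 2 (86.6), HSL-null array 1 (97.0) or HSL-null array 2 (97.2).

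Genes of the extracellular matrix were higher as a list. Of 23 fibroblast and matrix genes 0 were separated and 20 lay above 0, and the median of 0.14 lay above those of all 10000 random lists. Col1a1, a chain of type I collagen, measured 624 ± 23.5 (SD, n = 2 arrays) in wildtype and 870 ± 26.9 in HSL-null (log2 difference 0.48 ± 0.050, SE of duplicates), and Dcn, which encodes decorin, differed by 0.079 ± 0.020. The collagen genes Col1a2 at 0.36 ± 0.032 and Col3a1 at 0.37 ± 0.094 were chosen after their values were seen. The beta-actin ratio was higher in the same pool (0.819 against 0.697), but the Gapdh ratio was lower.

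Markers of other cell types lay inside the central 95%. The median was 0.036 for macrophages and monocytes (percentile 77.0), with C1qc at 0.036 ± 0.21 and Lyz2 at -0.075 ± 0.059. It was -0.047 for endothelium (percentile 22.0), with Eng at -0.047 ± 0.081 and Cdh5 at -0.0066 ± 0.059, and -0.12 for lymphocytes and mast cells (percentile 14.2), with Tpsb2 at -0.24 ± 0.090 and Cma1 at -0.15 ± 0.079. Smooth muscle and pericyte markers had a median of -0.0066 (percentile 57.1), with Des at -0.045 ± 0.0067 and Smtn at -0.090 ± 0.17. Schwann cell and nerve markers had a median of 0.20 (percentile 94.9), with Pmp22 at -0.032 ± 0.13 and Mbp at 0.20 ± 0.24. Erythroid markers had a median of 0.12 (percentile 91.9), with Hba-a1 at 0.12 ± 0.063 and Hbb-b2 at 0.089 ± 0.048. Satellite cell and denervation genes had a median of -0.045 (percentile 28.8), with Myf6 at -0.11 ± 0.034 and Des as above. Of the sex-linked genes 4 were on the array and 0 above the filter.

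Clock and immediate early genes were higher in HSL-null as lists. Dbp, a transcription factor driven by the circadian clock, measured 64.5 ± 2.76 (SD, n = 2 arrays) in wildtype and 106 ± 6.72 in HSL-null, 1.64-fold higher, and was the single separated member of 12 clock genes. The clock list had 8 members above 0 and 4 below, and its median was 0.16 (percentile 99.9). Egr1, an immediate early transcription factor, measured 53.1 ± 1.34 in wildtype and 93.4 ± 0.141 in HSL-null, 1.76-fold higher. It was the single separated member of 18 immediate early genes, of which 12 lay above 0 (11 with median centring or loess, 13 with quantile normalization). With the values as deposited, the median of the immediate early list was 0.11, at percentile 99.8. Both lists were higher in the pool with the higher beta-actin ratio (0.819 against 0.697), which had the lower Gapdh ratio. The immediate early list lay inside the central 95% with the filter at the 75th percentile (62.7), without wildtype array 2 (90.9) and without HSL-null array 2 (94.3).

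Lists of glucose metabolism, stress and growth lay inside the central 95%. Pfkfb3, which makes the activator of phosphofructokinase, differed by 1.11 ± 0.18 and was the single separated gene of 15 in glycolysis (median 0.052, percentile 88.8). Med1, a Mediator subunit that binds nuclear receptors, differed by 1.28 ± 0.15 and was the single separated gene of 11 among regulators of mitochondrial biogenesis and PPAR (median 0.040, percentile 79.0). Glycogen metabolism had a median of 0.018 (percentile 59.7), with Pygm at 0.024 ± 0.057 and Gys1 at -0.054 ± 0.022. Insulin signalling and glucose uptake had a median of -0.084 (percentile 7.84), with Slc2a4 at -0.056 ± 0.099 and Akt2 at -0.16 ± 0.061. The antioxidant list had a median of 0.0071 (percentile 61.0) and a mean of the opposite sign, -0.040, with Gstp1 at 0.038 ± 0.043 and Prdx2 at 0.057 ± 0.030. Proteolysis and muscle growth had a median of -0.045 (percentile 8.63), with Ctsd at -0.14 ± 0.052 and Ube2b at 0.14 ± 0.049. The unfolded protein and heat shock response had a median of -0.016 (percentile 32.9), with Hspa8 at -0.095 ± 0.17 and Hspd1 at -0.0094 ± 0.065.

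**Figure D1:**
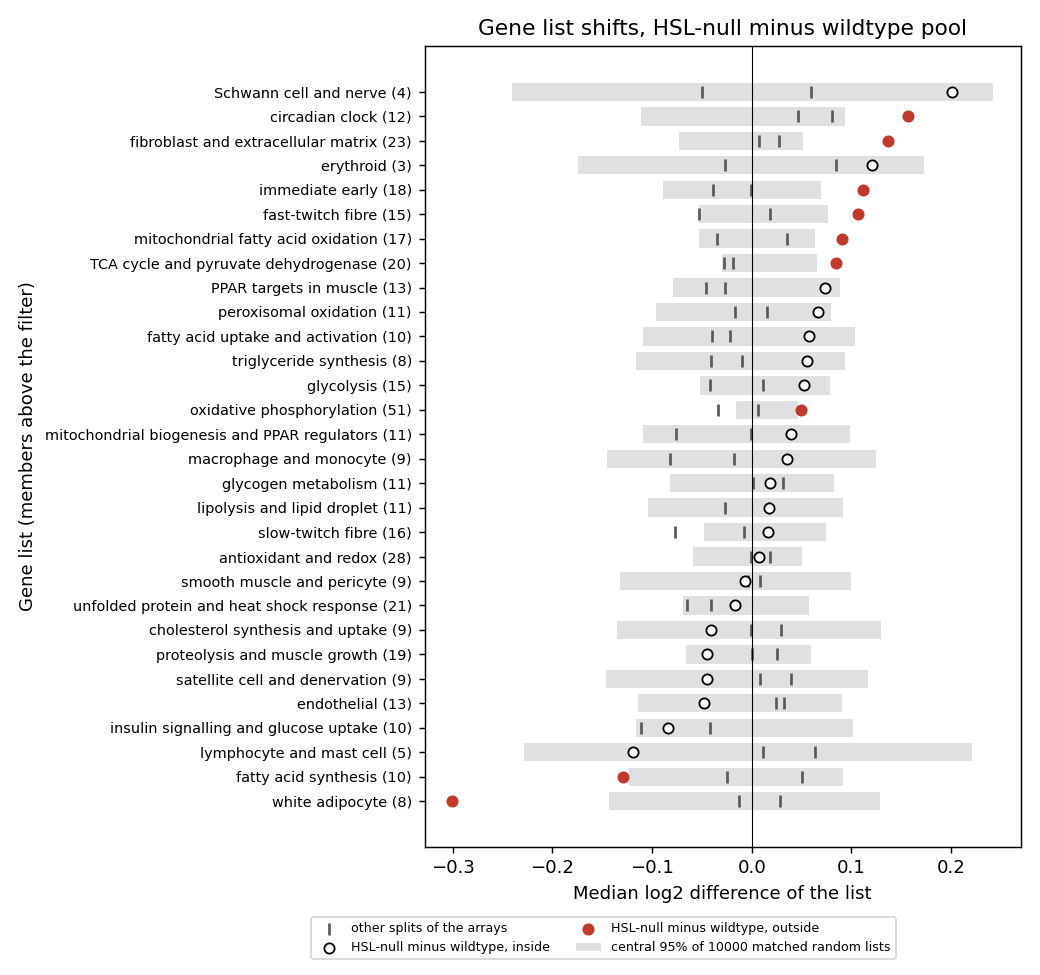
Median log2 difference, HSL-null minus wildtype (x axis), of 30 gene lists (y axis, members above the filter in brackets), with grey bars for the central 95% of 10000 matched random lists and ticks for the 2 other splits of the arrays. The 9 lists drawn as filled red points lie outside their grey bars, from white adipocyte at -0.30 to circadian clock at 0.16.

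The remaining separated genes with a symbol belonged to none of the lists. Higher in HSL-null were Ift46, an intraflagellar transport component (2.07 ± 0.26), the class Ib histocompatibility gene H2-M10.1 (2.02 ± 0.26), the serine protease inhibitor Serpina3n (1.05 ± 0.23), the polysialyltransferase St8sia4 (1.04 ± 0.21) and the serine hydrolase Bphl (0.71 ± 0.059). Lower were the RNA-binding protein gene Rbm4b (-2.53 ± 0.70), the transcriptional repressor Hic1 (-1.69 ± 0.42), Ccne1, which encodes cyclin E (-1.56 ± 0.11), and Cdo1, which encodes cysteine dioxygenase (-1.52 ± 0.080). Also lower were the phosphodiesterase gene Gdpd3 (-1.32 ± 0.21), the peptide-amidating enzyme Pam (-0.90 ± 0.061), the cytochrome P450 gene Cyp2e1 (-0.88 ± 0.092) and the glucocorticoid-induced co-chaperone Fkbp5 (-0.70 ± 0.064). Polb, which encodes a DNA polymerase (-0.69 ± 0.027), and a probe set missing from the annotation used here, 4.16-fold lower from 447 ± 10.5 (SD, n = 2 arrays) to 107 ± 1.34, were separated too and are named after their values were seen. Without a symbol, that probe set could not be checked against the lists, and it may belong to one of them. Other probe sets of the same gene above the filter were not separated for Ift46 (-0.30 ± 0.23), Hic1 (-0.050 ± 0.32) and Bphl (0.21 ± 0.14). For Ift46 and Bphl these were brighter than the probe sets named, at 98.1 against 15.5 and 90.9 against 30.7 in wildtype. Below the filter, the other probe sets of H2-M10.1 gave -1.03 ± 0.51, opposite on all 4 array pairs to the one named, and 0.31 ± 0.55, and those of Hic1 0.47 ± 0.75 and of Bphl -0.064 ± 0.46 and 0.12 ± 0.18 (another lay at the floor). The H2-M10.1 probe set named is of a kind that can share probes with related sequences.

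**Figure D2:**
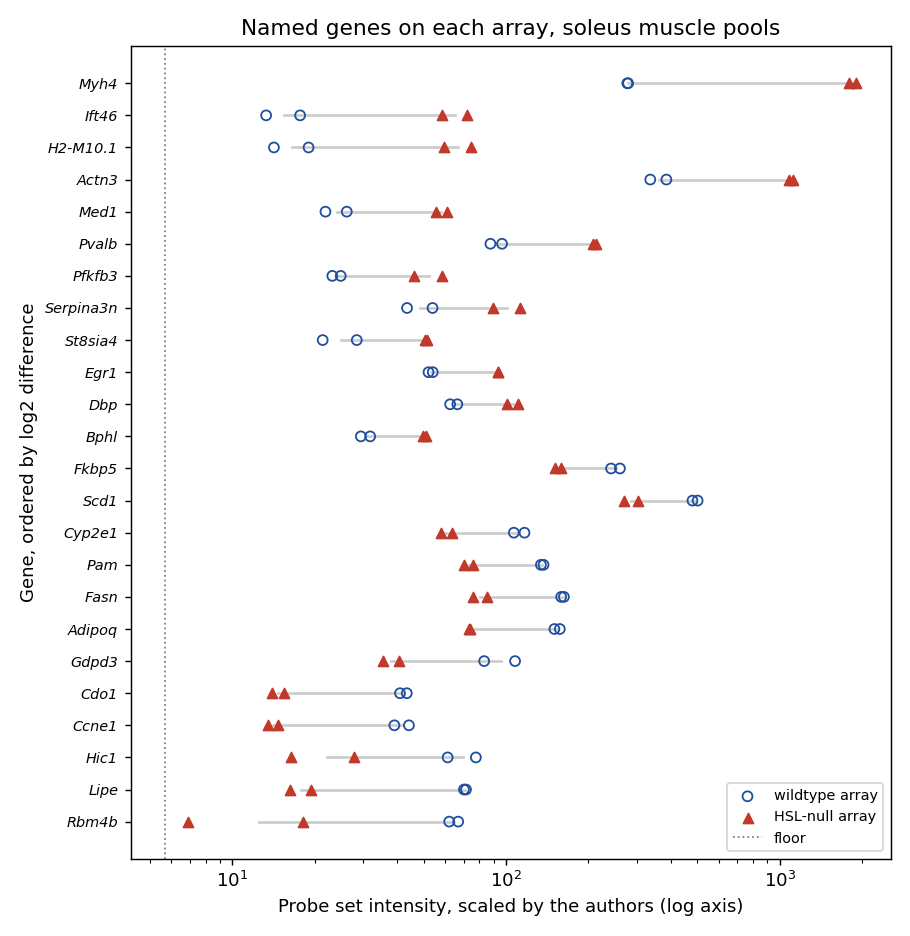
Intensity on each array (x axis, log scale, as deposited) for the 24 named genes (y axis, ordered by log2 difference), with open circles for wildtype arrays, triangles for HSL-null arrays, a grey line between the pool means and a dotted line at the floor of 5.7. The arrays of the genotypes do not overlap for any gene drawn, which follows from drawing only separated genes. Myh4 has the widest gap in intensity, from 278 to 1839.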

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

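The comparison of control probe sets in this part was chosen after the values were seen. The Bacillus poly-A control probe sets (Lys, Phe, Thr and Trpn, 12 in all), which no gene comparison uses, read higher on HSL-null array 2 than on the wildtype arrays, by a median log2 difference of 0.95 from the wildtype mean (1.93-fold, SD 0.28 over the probe sets). On HSL-null array 1 the difference was 0.19, so that these duplicates of a single pool differ in the control signal. The 9 hybridization control probe sets lay at 0.063 on HSL-null array 1 and at -0.14 on HSL-null array 2, against 0.20 and -0.20 on the wildtype arrays.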

How the results depend on the processing

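Lists without Lipe were the single alternative chosen after the data were seen. Against 28 separated probe sets (14 higher, 14 lower), other scalings and floors gave 26 to 29, of which 26 to 28 were shared. Without the filter there were 175 (120 higher, 55 lower), but the other splits then gave 129 and 134. With the filter at the 75th percentile there were 10 (5 and 5), since fewer probe sets were examined. A 1.2-fold threshold gave 226 (117 and 109), against 74 and 149 under the other splits, and a 2-fold threshold 14 (6 and 8), against 5 and 1. Leaving out an array leaves 2 differences to meet the rule and gave 82 to 109 (29 to 65 higher, 36 to 54 lower): 109 without wildtype array 1, 82 without wildtype array 2, 93 without HSL-null array 1 and 82 without HSL-null array 2. With the replicate number as a block (replicate block), 35 were separated. The left-out arrays and the block test differences that the rule had already required of the 28, so that keeping them shows no stability. The numbers were not taken to pair the arrays: differences between duplicates correlated between the genotypes at r = -0.086 across probe sets, and no label ties the numbers together. Lipe moved from -2.00 to -1.34 with the floor at the median of all values and -1.71 with a pseudocount, both of which compress low values. Median centring gave list medians of 0.057 for fatty acid oxidation, 0.051 for the TCA cycle, 0.016 for oxidative phosphorylation, 0.12 for the clock and -0.16 for fatty acid synthesis. Quantile normalization gave 0.060 for fatty acid oxidation, 0.052 for the TCA cycle, 0.012 for oxidative phosphorylation and 0.14 for the clock, whose median was 0.14 with loess and 0.14 with a pseudocount. The filter at the 75th percentile gave -0.55 for white adipocyte and 0.00046 for immediate early genes. With each array left out in turn, medians were 0.13 to 0.20 for the clock, 0.052 to 0.15 for immediate early, -0.38 to -0.27 for white adipocyte, -0.17 to -0.12 for fatty acid synthesis, 0.063 to 0.12 for fatty acid oxidation and 0.070 to 0.12 for the TCA cycle. The number of lists outside the central 95% was 9, and 6 to 10 under 18 alternatives. The highest count exceeds 9, so that at least a single list given above as inside moved outside under an alternative. The white adipocyte, matrix, clock and fatty acid oxidation lists lay outside under each alternative run. Of 306 values of named genes under alternatives, 17 moved by more than 1 SD of the duplicates, and their direction was largely fixed by how the genes were selected. Of 353 medians of the 21 lists inside the central 95%, 38 moved by more than 1 SD. Duplicates differed more where low signal was included: the SD of their log2 difference was 0.37 (wildtype) and 0.38 (HSL-null) without the filter and 0.17 and 0.16 at the 75th percentile, where r was 0.991 and 0.992, against 0.986 for HSL-null without the filter. For the other changes the cause was not tested.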

Other observations

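The tests of the clock, fibre and adipocyte patterns were chosen after the results were seen, and the test of the neighbours of Lipe before. A difference caused by the genotype, and chance differences between the mice of the pools, stay open and untested for each pattern.

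Of 12 clock genes above the filter, 8 lay above 0 in HSL-null (Dbp 0.71, Per1 0.63, Nr1d1 0.50, Tef 0.40, Per3 0.17, Nr1d2 0.16, Cry2 0.15, Cry1 0.10) and 4 below (Arntl -0.52, Clock -0.14, Bhlhe40 -0.092, Nfil3 -0.041). Noise between arrays stays open: the median size of the 12 differences, 0.17, lay at percentile 96.7 and 99.5 of level-matched random lists under the other splits of the arrays, short of the 99.8 that a search over 30 lists needs. Collection of the pools at different times of day may shift the clock. The median of the other 9 genes lay 0.32 above that of Arntl, Clock and Nfil3, which peak in a phase opposite to most of them. From the pool means, the median of these 3 was the value of Clock (-0.14). The gap was 0.41 to 0.71 on single array pairs, where the middle gene can be another, and -0.043 and -0.059 under the other splits. These arms were drawn after the values were seen, however, and Bhlhe40 went against its arm. Different collection times and an effect of the genotype on the clock cannot be told apart, because the labels give no times.

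Of 15 fast-twitch genes, Myh4, Actn3 and Pvalb were separated higher in HSL-null and 12 were not separated. A fault of single probe sets is argued against for Actn3, whose second probe set was higher by at least 0.63 on each array pair. That second probe set has the suffix _f and can share probes with related sequences, which limits this check. Such a fault stays open for Myh4, whose second probe set differed by as little as -0.037 but lay close to the filter. Noise between arrays stays open for the list, whose differences had a median size of 0.11. This lay at percentile 99.2 and 100 of level-matched random lists under the other splits, against the 99.8 needed. The measure takes no account of sign, with 14 genes above 0 and 1 below, and gives little weight to the 3 separated genes. Their smallest differences on any array pair were 2.67 (Myh4), 1.48 (Actn3) and 0.70 (Pvalb, brighter probe set). Under another split of the arrays, however, the signed median of the list was -0.053, at percentile 1.74. Fast muscle carried over in the dissection could raise these genes and would dilute slow-fibre genes, whose median was 0.016 (-0.057 to 0.10 over the array pairs), with 4 of 16 below 0 on all 4 pairs (6 with quantile normalization, 4 with each other scaling) and 3 above 0 (0 with median centring or quantile normalization). Carry-over cannot be told apart from a change of fibre type, because either could raise fast-fibre genes and lower slow-fibre genes. In addition, the slow-fibre median took no direction, and the brightest slow-fibre members lie near the highest intensity on the arrays.

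The white adipocyte markers and the fatty acid synthesis genes were lower in HSL-null as lists, with 2 of 8 and 1 of 10 separated. Noise between arrays is argued against for the 7 markers other than Lipe, whose differences had a median size of 0.35, at percentile 100 of level-matched random lists under both other splits, though this measure takes no account of sign and Agt was higher (0.98). It may account for the fatty acid synthesis genes as a list, whose median size of 0.13 lay at percentile 84.8 and 97.1, though the measure gives no weight to all 10 lying below 0. Less adipose tissue in the HSL-null pool could lower the markers together, and those other than Lipe and Adipoq had a median of -0.22 (-0.28 to -0.19 over the array pairs), far from the -1.06 of Adipoq. Fewer adipocytes and lower expression within them cannot be told apart, because muscle tissue expresses some of these markers itself and 2 of them are also fatty acid synthesis genes.

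Of the 100 genes on either side of Lipe, 21 were above the filter and 0 of these were separated. The SD of their log2 differences was 0.16, at percentile 34.6 of 10000 random stretches of as many neighbouring genes (median 0.18). The largest of these differences was 0.38 in size. This argues against large changes of expression from passenger alleles, among these 21 genes only. Small changes in single genes could be missed, since the rule recovered 14% of simulated 1.5-fold changes and the SD covers all 21. A passenger segment can reach beyond this window. Genes further from Lipe were not tested, and the separated genes were not placed relative to Lipe, so that passenger alleles there stay open.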
